A study of Homo sapiens with 4 samples.

How the data were processed

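Expression was measured on 4 Affymetrix arrays of HCT116 cells, a human colorectal carcinoma cell line: 2 arrays of cells infected with a retroviral vector expressing the microRNA miR-34a and 2 arrays of cells infected with the empty vector. Per the labels' protocols, infected cells were kept under puromycin (1 ug/mL) for 2 weeks to select them, and labelled cRNA was made from 5 ug of total RNA. The labels call the arrays of each group technical replicates. The groups therefore rest on no labelled independent infections, and every p-value below measures the technical spread between these arrays, not the spread between cultures.

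The deposited values are 1 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its scaling target and its detection calls are not given in the sources used here. After 2% of the values were trimmed at each end, the mean deposited intensity was 150.02 on each of the 4 arrays, and the values were used without further scaling. The table held 54675 probe sets, of which 62 were controls and 4 had a missing value on at least 1 array. These were left out of the tests. No depth exists for arrays; their number limits the precision.

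Gene names came from the platform annotation given with the values. Of the probe sets other than controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none listed; no gene was named from the last 2 kinds. Symbols were checked through gene identifiers against the RefSeq gene table of GRCh38.p14, in which 41037 of the 41091 probe sets matched, and 0 symbols needed updating. A gene missing from that annotation is unnamed here and was not analysed. No genome build is named for the values, so no coordinates are given.

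The tests, filters and gene lists in this paragraph were chosen before the data were examined. Signals were transformed as log2(signal + 20), so a fold change here is on that scale and understates the change of dim genes. A probe set was tested if its mean signal over all 4 arrays was at or above the median of that mean, which was 37.95. Each gene was represented by its probe set with the highest mean signal over the 4 arrays. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment over 12734 genes and an adjusted p threshold of 0.05. Genes past it are said to have risen or fallen in the miR-34a arrays. Positive changes are higher in the miR-34a arrays. For 24 gene lists, the median log2 change of the tested members was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list outside the central 95% of those medians is said to stand apart. This percentile describes these arrays and is not a p-value. Chance would put about 1.2 of 24 lists outside if members of a list moved independently of one another. Genes that are regulated together do not, and some lists share genes, so more lists can lie outside without a cause of their own. Lists include markers of fibroblasts and leukocytes, and housekeeping genes.

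The genes named in the text are the 8 largest rises and the 8 largest falls among genes that passed the test, whose arrays of one group all lay beyond those of the other and whose brighter group mean was above the median signal of tested genes (233.3). To these were added the 2 members with the largest change among those that passed in each list (or the member with the largest moderated t where none passed), and CDKN1A, CDK6, CDK4, CCND1, CCNE2, E2F3, MET and BCL2 whatever their values.

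The test was checked on data simulated for this comparison with the 12734 tested genes, their mean signals and the spread between the arrays. A first simulation with a coarser model of that spread gave 0 calls, and the spread was then drawn from the variance distribution that limma estimates within 20 bins of signal, with larger and more numerous changes. With 200 genes changed, 47% of those changed 2-fold and 95% of those changed 4-fold were called, and 3 of 145 calls were false. With 2600 genes changed, 54.9% of those changed 1.5-fold and 87.5% of those changed 2-fold were called, and 67 of 1917 calls were false. Among 200 simulated lists of 25 unshifted genes, 4% stood apart, and 100% of 50 lists shifted by 0.5 on the log2 scale did. These lists held random genes from the simulation with 200 changed genes. The 4% therefore does not cover genes regulated together. The 100% may be too high for the data, where more genes were called and most lists had fewer than 25 tested genes.

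The replicate numbers are shared between the groups, but the labels do not say that a number marks a shared batch. The deviations of same-numbered arrays correlated across genes at 0.063, and the arrays were treated as unpaired. Alternatives covered the pseudocount, the signal filter, quantile, median and cyclic loess normalization, other choices of probe set, an intensity trend or a minimum fold in the test, a replicate block and leaving out each array. The planned search of 3' UTRs for miR-34a seed matches was not run, since no transcript sequences were used here.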

Results

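Gene expression was compared between HCT116 cells carrying a retroviral miR-34a vector and cells carrying the empty vector, to find transcripts that respond to this microRNA. Each group had 2 arrays, labelled as technical replicates. Median signals of the 4 arrays lay between 37.5 and 40.7 over all probe sets, and single signals ranged from 0.1 to 18928.3. On the log2 scale, arrays of one group correlated at 0.976 for miR-34a and 0.978 for empty vector, and arrays of different groups at 0.960 to 0.963, across probe sets. The median absolute difference between the group means was 0.26 per gene, against 0.13 between the single arrays of either group. Means of 2 arrays vary less than single arrays, so these values are not on the same footing. The mature microRNA is not measured by these arrays, so its level could not be checked. The 3' to 5' signal ratio of the GAPDH control probe sets was 0.835 ± 0.016 (SD, n = 2) in miR-34a arrays and 0.948 ± 0.025 (SD, n = 2) in empty vector arrays. For actin it was 1.28 ± 0.014 and 1.37 ± 0.053 (SD, n = 2 each).

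Among genes whose brighter group mean was above 233.3, most of the 8 largest rises in the miR-34a arrays were in genes of DNA synthesis and mitosis. RRM2, a subunit of ribonucleotide reductase, had a signal of 3175 ± 144 with miR-34a and 315 ± 12 with empty vector (SD, n = 2 each), a log2 change of 3.26 ± 0.10 (SE; adjusted p = 0.0031). KIFC1, a mitotic kinesin, rose from 13.8 ± 1.1 to 298 ± 6.3, but 34.0 to 36.3% of probe sets on each array were under 20 and no detection calls were used here, so the size of its rise and its place among the 8 are uncertain. CDCA3, CDC20, ZWINT and ASPM, which act in cell division, rose by 3.15, 3.01, 2.95 and 2.93 on the log2 scale; without shared and cross-hybridising probe sets the rise of ASPM was 1.45. The other 2 were KRTAP3-1, annotated as a keratin-associated protein gene (149 ± 44 to 1520 ± 79), and NMU, which encodes the peptide neuromedin U (265 ± 19 to 2222 ± 11). Under the same limit, the largest decreases were in TMEM158, which fell from 2262 ± 43 to 339 ± 5.2 (log2 change -2.67 ± 0.09, adjusted p = 0.0031), and in MMP1, an interstitial collagenase, which fell from 244 ± 4.1 to 22.1 ± 3.7, near 20 as well, so the size of its fall and its place are uncertain too. The log2 changes of the other 6 genes were -2.54 for LURAP1L, -2.52 for PYGB (glycogen phosphorylase), -2.44 for CHAC1, -2.36 for ASNS (asparagine synthetase), -2.33 for PLAU (urokinase) and -2.30 for SERPINA5. The fall of PYGB rested on 1 of its 2 tested probe sets; with the other, the log2 change was 0.16 and was not called.

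In all, 2677 of 12734 genes passed the test, of which 1254 rose and 1423 fell in the miR-34a arrays. At least 2-fold changes were found in 310 that rose and 284 that fell. The arrays of the groups did not overlap for 8222 genes. Chance gives 33.3% of genes if all 4 arrays are exchangeable, which technical replicates of different cultures are not, so the excess does not separate an effect of the vector from any other difference between cultures. Counts depended on having all 4 arrays. Without the first or the second miR-34a array, 727 and 567 genes passed; without the first or the second empty vector array, 0 passed in limma, with 3745 and 3718 at an unadjusted p under 0.05 and 3172 and 3059 with an intensity trend. No gene called with 4 arrays changed sign in any of these 4 fits. This says little about stability, since a gene whose groups do not overlap cannot change sign when an array is left out. Other choices of probe set did reverse some called genes. These were 20 of 2677 with the mean of probe sets and 55 of 2041 without shared and cross-hybridising probe sets. Without either empty vector array, 0 members of any of the 24 gene lists passed in limma with adjustment over all genes; adjusted over the list alone, some lists kept most of theirs.

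**Figure D1:**
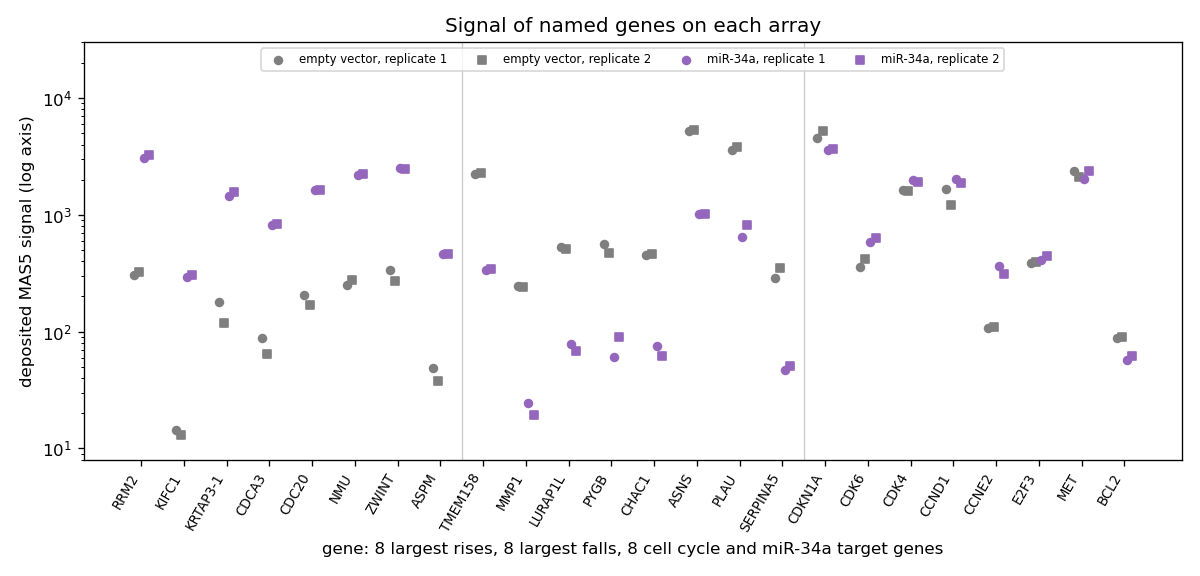
Deposited MAS5 signal on a log axis for each array, with gene symbols along the horizontal axis; gray is empty vector, purple is miR-34a, circles are replicate 1 and squares replicate 2. The 8 largest rises and the 8 largest falls among genes with a brighter group mean above 233.3 are at the left and in the middle, and 8 genes fixed in advance at the right, where only MET has overlapping groups.

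Cell cycle genes were higher in the miR-34a arrays as a group. All 28 tested members of the G2/M and mitosis list rose, with a median log2 change of 2.37, where 95% of matched random lists had medians from -0.20 to 0.15. CDC20, an activator of the anaphase-promoting complex, rose from 186 ± 26 to 1638 ± 3.7, and CCNB1, cyclin B1, from 197 ± 25 to 1500 ± 20 (SD, n = 2 each; adjusted p = 0.0031 for both). Of 33 tested genes of G1/S and DNA replication, 30 rose, 0 fell and 3 did not pass, with a median of 1.44. GINS2, a part of the replicative helicase, rose by 2.17 ± 0.10 (SE). The numbers that rose, adjusted over the list alone, were 28 and 31. The medians without 1 array stayed between 2.33 and 2.40 for G2/M and between 1.37 and 1.47 for G1/S. The number of called members was 25 or 26 and 23 or 24 without a miR-34a array, and 0 without an empty vector array; adjusted over the list alone, these last were 28 and 31 or 30. The GAPDH 3' to 5' ratio was lower in the same arrays (0.835 against 0.948).

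DNA repair genes also stood apart. Of 25 tested, 15 rose, 1 fell and 9 did not pass, with a median log2 change of 0.59 and 18 rising and 1 falling when adjusted over the list alone. RAD54B, a homologous recombination factor, rose from 91.5 ± 3.1 to 389 ± 0.99, and EXO1, an exonuclease, from 83.7 ± 9.4 to 304 ± 52 (SD, n = 2 each). Wnt/beta-catenin targets had a median of 0.38 over 12 genes, of which 4 rose, 1 fell and 7 did not pass. Among them, SP5 rose by 1.46 ± 0.26, a call lost without a pseudocount, and AXIN2 by 1.17 ± 0.17 (SE). Cholesterol synthesis genes had a median of 0.36 over 16 genes, with 6 rising and 0 falling; FDPS, farnesyl diphosphate synthase, rose by 0.68 ± 0.11 and IDI1 by 0.73 ± 0.12 (SE). The change of IDI1 was -0.10 and not called without probe sets marked as shared or cross-hybridising. Genes of ribosome biogenesis regulated by MYC had a median of 0.24 over 18 genes, with 5 rising, among them PES1 (0.91 ± 0.16), and 1 falling, RRP12 (-0.82 ± 0.09). The call of RRP12 was lost with the mean of its probe sets (-0.36) and without shared and cross-hybridising ones (-0.49). For Wnt targets 5 rose and 1 fell when adjusted over the list alone, for cholesterol genes 8 and 1, and for ribosome biogenesis 5 and 1. Without 1 miR-34a array, 8 or 7 DNA repair genes, 1 Wnt target, 0 cholesterol genes and 1 or 0 ribosome biogenesis genes rose, and 0 genes of these lists fell. Without 1 empty vector array, adjusted over the list alone, 18 or 15 DNA repair genes and 5 or 4 Wnt targets rose, 1 DNA repair gene fell, and 0 ribosome biogenesis genes passed. Whichever array was left out, 0 cholesterol genes passed, also when adjusted over the list alone. Without the filter on signal, 8 DNA repair genes, 1 Wnt target and 0 ribosome biogenesis genes rose. In that setting 1 ribosome biogenesis gene fell, 0 cholesterol genes passed, and the Wnt median was 0.20 and no longer stood apart (percentile 94.9).

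The joint list of the unfolded protein and integrated stress responses had a lower median in the miR-34a arrays, with members going both ways. Of 20 tested, 12 fell, 2 rose and 6 did not pass, with a median log2 change of -0.79 (95% of random lists, -0.18 to 0.24). CHAC1, a glutathione-degrading enzyme induced by ATF4, fell from 458 ± 2.5 to 68.6 ± 8.7, and ASNS from 5307 ± 99 to 1014 ± 0.49 (SD, n = 2 each; adjusted p = 0.0031 for both). The 2 that rose, named after their values were seen, encode proteins of the endoplasmic reticulum: CALR (0.74) and SDF2L1 (1.36). NF-kB and inflammatory genes had a median of -0.66 over 15 genes, of which 8 fell and 0 rose. The chemokine genes CXCL1 and CXCL2 fell, with log2 changes of -1.97 ± 0.10 and -1.84 ± 0.11 (SE). Leaving out probe sets marked as shared or cross-hybridising brought that median to -0.31 (percentile 4.49). Of 6 tested histone genes, 5 fell and 1 did not pass, with a median of -1.03. Without the signal filter the median was -0.58 over 13 histone genes, of which 2 fell. Only 2 histone genes were left without shared and cross-hybridising probe sets. Both fell (median -1.20), but they were too few for a percentile. The log2 changes of H2AC6 and H1-2 were -1.59 ± 0.10 and -1.27 ± 0.18 (SE). When adjusted over the list alone, 14 stress genes fell and 4 rose, 9 inflammatory genes fell and 6 histone genes fell. Without 1 miR-34a array, 9 stress genes, 6 or 4 inflammatory genes and 3 or 2 histone genes fell, and 1 stress gene rose. Without 1 empty vector array, 13 stress genes, 6 or 7 inflammatory genes and 5 histone genes fell and 3 stress genes rose when adjusted over the list alone.

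Angiogenesis genes had a median log2 change of -0.46 over 17 genes, of which 8 fell, 2 rose and 7 did not pass. PLAU fell from 3714 ± 132 to 729 ± 124 (SD, n = 2 each), and NRP1, a co-receptor for VEGF, with a log2 change of -1.75 ± 0.20 (SE). This list no longer stood apart without the signal filter (-0.19, percentile 2.89) or without shared and cross-hybridising probe sets (-0.18, percentile 13.85). TGF-beta response genes had a median of -0.33 over 18 genes, with 9 falling and 3 rising, -0.22 with a pseudocount of 100 and -0.50 over 11 genes without shared and cross-hybridising probe sets. PMEPA1 and SKIL, both induced by TGF-beta, fell, with log2 changes of -1.55 ± 0.11 and -1.51 ± 0.16 (SE). AP-1 and immediate early genes had a median of -0.21 over 24 genes, with 5 falling, 1 rising and 18 not passing. FOSL1, an AP-1 subunit, fell from 2021 ± 113 to 591 ± 27, and DUSP5, a phosphatase of ERK, from 3517 ± 64 to 1328 ± 37 (SD, n = 2 each). As adjusted over the list alone, 8 angiogenesis genes fell and 2 rose, 9 TGF-beta response genes fell and 3 rose, and 7 AP-1 genes fell and 1 rose. With either miR-34a array left out, 5 angiogenesis genes, 2 TGF-beta response genes and 2 AP-1 genes fell, and 0 rose. With either empty vector array left out, the list-alone counts were 8 angiogenesis genes, 9 or 8 TGF-beta response genes and 2 AP-1 genes falling, and 3 or 2, 2 and 0 rising.

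The p53 target list had a median log2 change of -0.23 over 30 genes, of which 5 fell, 1 rose and 24 did not pass. GADD45A and SESN2 fell, with log2 changes of -1.61 ± 0.09 and -1.14 ± 0.12 (SE); both are also induced by stress signalling through ATF4, and SESN2 is in the stress list too. CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, had signals of 3624 ± 44 with miR-34a and 4855 ± 485 with empty vector and did not pass (log2 change -0.42 ± 0.11, adjusted p = 0.064); it passed with quantile or cyclic loess normalization, a pseudocount of 100, a stricter signal filter or an intensity trend. Apoptosis genes had a median of -0.23 over 27 genes, with 8 falling, 1 rising and 18 not passing. The list mixes genes that promote apoptosis with genes that inhibit it, so its median gives no direction for apoptosis. The death receptor gene TNFRSF10B fell, with a log2 change of -1.02 ± 0.09, as did HRK, a pro-apoptotic BCL2 family member, with -0.99 ± 0.23 (SE). The other fallers, named after their values were seen, include inhibitors: MCL1 (-0.89), BIRC2 (-0.79), XIAP (-0.53) and BCL2 (-0.46). TNFRSF10A (-0.93) and CASP8 (-0.51), which promote apoptosis, fell too. The call of HRK was lost without a pseudocount and without shared and cross-hybridising probe sets (-0.43). Adjusted over the list alone, 7 p53 targets fell and 1 rose, and 10 apoptosis genes fell and 2 rose. With 1 miR-34a array left out, 3 p53 targets and 1 or 2 apoptosis genes fell, and 0 rose. With 1 empty vector array left out, 4 or 3 p53 targets and 5 or 7 apoptosis genes fell, and 1 or 0 and 0 or 1 rose, adjusted over the list alone. Both medians depended on single arrays: without the first miR-34a array the p53 median was -0.084 (percentile 13.8) and the apoptosis median -0.079 (percentile 25.1), without the first empty vector array the apoptosis percentile was 2.55, and without the second empty vector array the p53 percentile was 3.22.

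Among 37 tested genes that have been reported as miR-34a targets, 8 fell, 5 rose and 24 did not pass. The median log2 change was -0.15, at percentile 2.38 of matched random lists, whose central 95% ran from -0.15 to 0.16. Adjusted over the list alone, 10 fell and 5 rose. With either miR-34a array left out, 5 fell and 2 rose; with an empty vector array left out, 5 or 6 fell and 2 or 4 rose when adjusted over the list alone. Some members may have been chosen from these same arrays, so the list is not independent evidence of its direction. KLF4, a transcription factor of epithelial differentiation, fell from 2117 ± 29 to 594 ± 58, and BIRC5, survivin, rose from 128 ± 20 to 952 ± 8.2 (SD, n = 2 each). The median no longer stood apart under most other settings, with percentiles of 27.4 without the first miR-34a array, 6.80 without the second, 13.5 without the first empty vector array and 33.0 without the signal filter.

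The genes fixed in advance were chosen as cell cycle genes and miR-34a targets. Of these, CCNE2, cyclin E2, rose from 108 ± 1.4 to 338 ± 35 (SD, n = 2 each; log2 change 1.48 ± 0.11 SE, adjusted p = 0.0053). CDK6 rose from 389 ± 41 to 609 ± 31 (0.62 ± 0.12, adjusted p = 0.029), with 3 of its 5 other tested probe sets in the same direction and a mean over all probe sets of 0.14, which was not called. BCL2, an inhibitor of apoptosis, fell from 89.7 ± 1.1 to 59.7 ± 3.3 (-0.46 ± 0.09, adjusted p = 0.035), a call that was lost with an intensity trend. CDK4 (0.28 ± 0.09, adjusted p = 0.097), CCND1 (0.45 ± 0.18, adjusted p = 0.15), E2F3 (0.11 ± 0.10, adjusted p = 0.45) and MET (-0.031 ± 0.13, adjusted p = 0.89) did not pass. With an intensity trend, CDK4 and CCND1 passed, as did CDK4 with a pseudocount of 100 or a stricter signal filter.

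**Figure D2:**
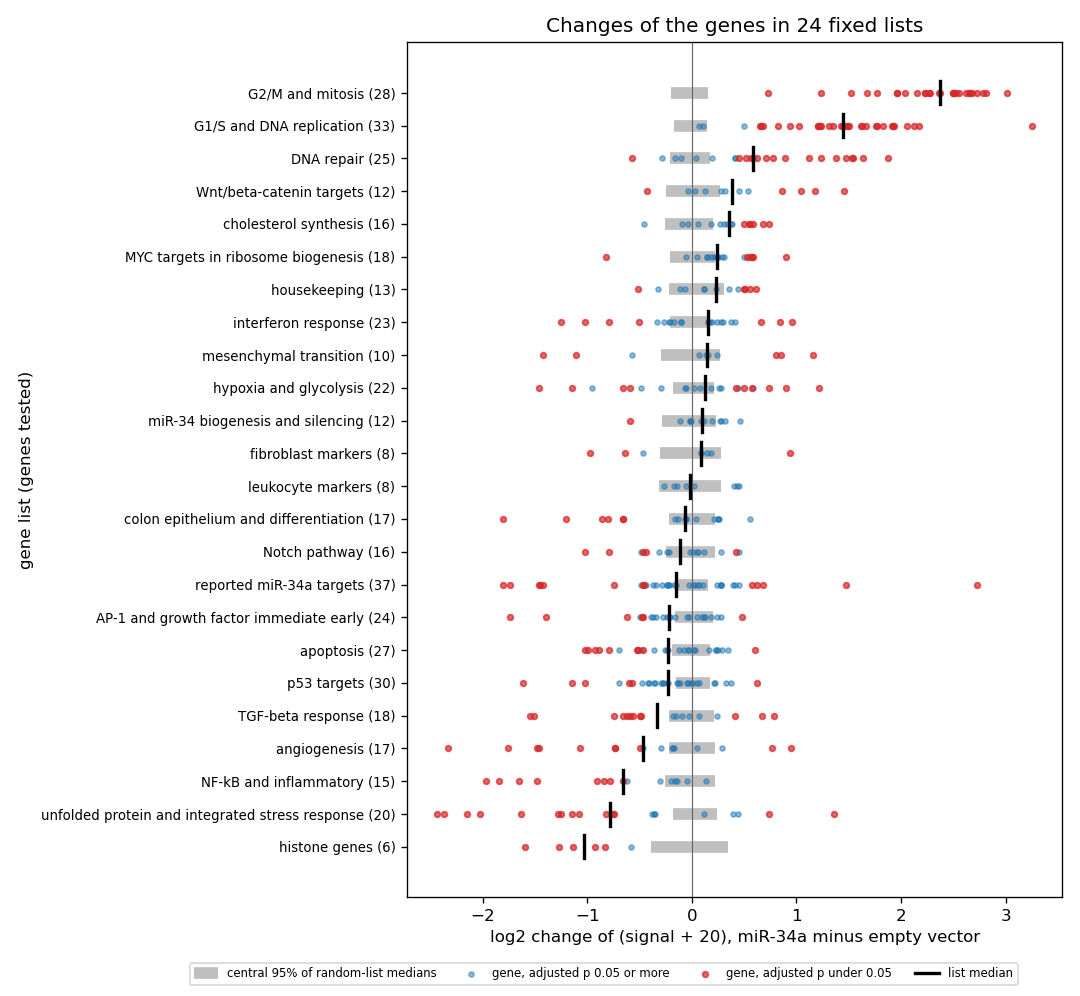
Log2 change of each tested gene (points; red where the adjusted p is under 0.05, blue otherwise) and the median (black bar) for 24 gene lists on the vertical axis, with the number of genes tested. Gray bands hold the central 95% of medians of matched random lists; G2/M genes (median 2.37) lie farthest to the right; histone genes (-1.03) and stress genes (-0.79) lie to the left.

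The remaining 9 lists did not stand apart. Interferon response genes had a median of 0.16 (percentile 96.1) and a mean of -0.0099, with 3 rising and 4 falling of 23. BST2, whose miR-34a signal was only 17.7 ± 9.5 (SD, n = 2), and IFI35 (-1.02), both induced by interferon, fell; the call of BST2 was lost without a pseudocount. Hypoxia and glycolysis genes went both ways, with 6 rising and 4 falling of 22: the log2 change was 1.22 ± 0.11 for SLC2A1, a glucose transporter, and -1.46 ± 0.09 for VEGFA (SE). Of 16 Notch pathway genes 4 fell and 1 rose, with HEY1 (-1.02) and HES1 (-0.79), transcription factors induced by Notch, among those that fell. Of 17 genes of colon epithelium 6 fell and 0 rose, including KLF4 and CDH1, E-cadherin (1035 ± 47 to 440 ± 36, SD, n = 2 each). With a stricter filter on signal, this list stood apart with a median of -0.65. Of 10 mesenchymal genes 3 rose and 2 fell; S100A4 (1.16) was among those that rose and AXL (-1.42) among those that fell. Of 12 genes of microRNA processing and silencing, 1 fell, AGO4 (-0.59 ± 0.10 SE), a call lost with the mean of its probe sets (-0.38). The rising and falling genes adjusted over the list alone numbered 4 and 4 for interferon, 8 and 6 for hypoxia, 1 and 4 for Notch, 1 and 6 for colon epithelium, 3 and 3 for mesenchymal genes, and 0 and 1 for microRNA processing. With 1 miR-34a array left out, those that passed over all genes numbered 0 rising and 1 or 0 falling for interferon, 2 or 1 and 2 for hypoxia, 0 and 1 for Notch, 0 and 2 or 3 for colon epithelium, 1 and 2 for mesenchymal genes, and 0 and 0 for microRNA processing. Without 1 empty vector array, the list-alone numbers rising and falling were 2 or 3 and 0 or 2 for interferon, 6 or 9 and 3 or 5 for hypoxia, 0 and 2 for Notch, 0 and 6 or 5 for colon epithelium, 4 or 2 and 2 for mesenchymal genes, and 0 and 0 for microRNA processing.

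The lists of markers of other cell types did not stand apart with all probe sets. Fibroblast markers had a median of 0.087 and a mean of -0.079 over 8 genes, with 1 rising (FBLN1, 0.94) and 2 falling (among them COL6A3, -0.98, a call lost without a pseudocount). The change of FBLN1 was -0.39 and not called on another probe set. Without probe sets marked as shared or cross-hybridising, the fibroblast list had a median of -0.52 over 4 genes and stood apart (percentile 1.27). Leukocyte markers had a median of -0.014 and a mean of 0.085, and 0 of 8 passed in limma, with HLA-DRA at 0.45 ± 0.13 (SE; adjusted p = 0.076). Housekeeping genes had a median of 0.23 over 13 genes (percentile 92.8), with 4 rising and 1 falling. PPIA, cyclophilin A, rose from 8573 ± 495 to 13084 ± 375, and POLR2A from 357 ± 14 to 536 ± 20 (SD, n = 2 each). Without the second empty vector array the housekeeping median was 0.35 and stood apart (percentile 98.8). Adjusted over the list alone, rising and falling genes numbered 1 and 2 for fibroblast markers, 0 and 0 for leukocyte markers and 6 and 2 for housekeeping genes. With 1 miR-34a array left out, 1 or 0 fibroblast markers fell, 0 or 1 leukocyte markers rose and 0 housekeeping genes passed. With 1 empty vector array left out, 1 fibroblast marker rose, and 0 leukocyte markers and 0 housekeeping genes passed, when adjusted over the list alone.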

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

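A signal outside the gene-level comparison was found in probe sets that carried no gene name or several. Each probe set was tested with limma, with adjustment over all tested probe sets. Of 4254 such probe sets, 196 were higher and 180 lower in the miR-34a arrays at an adjusted p under 0.05. These 376 are a smaller share than the 2677 called of 12734 genes, but the shares come from unlike tests. Each gene was represented by its probe set with the highest mean signal, and adjustment there was over genes, not over all probe sets. Changes of at least 2-fold were found in 61 of the higher and 53 of the lower. The largest rise among them was from 197 ± 26 to 1506 ± 32 (SD, n = 2 each), a log2 change of 2.82 (adjusted p = 0.0066). The largest fall among them was from 1732 ± 9.2 to 221.5 ± 4.1, a log2 change of -2.86 (adjusted p = 0.0066), which is beyond the largest fall among all 12734 genes tested (-2.67). Groups of 2 arrays are too small to test for a single outlying array.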

How the results depend on the processing

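The splits of the reported targets and of the added families by membership in other lists were chosen after seeing the data, the other alternatives before, and the cause of each change was not tested unless stated. The number of genes called (2677, of which 1254 rose and 1423 fell) was 774 (377 and 397) with no signal filter, 1687 (766 and 921) without probe sets whose names end in _x_at or _s_at, 4111 (1966 and 2145) with an intensity trend, 273 (157 and 116) with a tested minimum of 1.5-fold, 594 (310 and 284) at 2-fold or more, and 1730 (825 and 905) with the replicate number as a replicate block; the fewer calls with a minimum fold follow from its construction. Without 1 array, the counts ranged from 0 to 727, from 0 to 315 rising and from 0 to 412 falling, where a fit has 1 residual degree of freedom and the lone array is assumed to vary like the other group. The reported miR-34a targets (median -0.15) lost their place outside the random lists with no pseudocount (-0.16, percentile 2.90), a pseudocount of 100 (-0.076), no filter (-0.025), a stricter filter on signal (-0.011), quantile normalization (-0.14), cyclic loess (-0.13) and without _x_at and _s_at probe sets (-0.17); without 1 array they ranged from -0.17 to -0.048. Their median was -0.19 without genes of the G1/S or G2/M lists and -0.23 without genes of any other list, both still apart. Apoptosis genes (-0.23) did so with a pseudocount of 100 (-0.10), no filter (-0.12), the stricter filter (-0.13), the mean of probe sets (-0.16) and without _x_at and _s_at probe sets (-0.22), and ranged from -0.28 to -0.079 without 1 array; p53 targets ranged from -0.26 to -0.084 and housekeeping genes from 0.18 to 0.35. Angiogenesis genes did so with no filter (-0.19) and without _x_at and _s_at probe sets (-0.18), Wnt targets with no filter (0.20) and NF-kB genes without _x_at and _s_at probe sets (-0.31). Colon epithelium genes came to stand apart with the stricter filter (-0.65), and fibroblast markers turned from 0.087 to -0.52 without _x_at and _s_at probe sets and then stood apart (percentile 1.27); in that setting PYGB (0.16), IDI1 (-0.10) and FBLN1 (-0.39) also turned. MET, which was not called, ranged from -0.14 to 0.083 without 1 array. Of 1057 comparisons of named genes with an alternative, 826 kept direction and side of the threshold, 217 lost and 9 gained the call, and 5 changed direction. The pairing was a shared number only (correlation 0.063). Alternatives for 3' UTR seed matches were not run, since no transcript sequences were used here.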

Other observations

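Gene families were chosen after the largest changes had been seen, and some share genes with the lists above, so they are no independent evidence for those lists. All 12 tested mitotic kinesins rose (median log2 change 2.30), while the 17 other kinesins had a median of 0.12, with 2 rising and 0 falling (in limma, adjusted p under 0.05). Without 4 mitotic kinesins that are in a list above or among the 8 largest rises, the 8 left all rose (median 1.97). Of 14 condensin and cohesin genes 9 rose and 0 fell (median 1.04), and of 21 nucleotide synthesis genes 11 rose and 0 fell (0.57; 0.43 over 15 that are in no list above). Among 28 splicing factors 13 rose and 0 fell (0.36), among 36 proteasome subunits 11 rose and 1 fell (0.27), among 32 subunits of respiratory complex I 7 rose and 0 fell (0.29), among 75 mitochondrial ribosomal proteins 15 rose and 1 fell (0.19), and among 21 nucleoporins 7 rose and 0 fell (0.24). Each of these medians lay above the central 95% of matched random lists, except that of the other kinesins.

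Of 24 genes of the amino acid response that ATF4 induces, 19 fell and 0 rose (median -1.03), but 8 of them are in a list above, 2 of these among the 8 largest falls. Of the other 16, 11 fell and 0 rose (median -0.77). Of 16 serpins 6 fell and 0 rose (median -0.29); without SERPINA5, 1 of the 8 largest falls, the median was -0.27 (percentile 1.49) with 5 falling. The 53 cytosolic ribosomal protein genes had a median of -0.080 (percentile 1.01) with 0 rising and 1 falling, RPL10L having the lowest value (-0.56). Keratins (-0.025), lysosomal genes (-0.050), zinc finger genes named ZNF (-0.041) and MAPK phosphatases with ETS factors (-0.18) lay within the central 95%.

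The tests of exchanged labels, of RNA integrity, of an amino acid response and of neighbouring genes in the paragraphs that follow were chosen after related values had been seen. The first pattern is that cell cycle genes were higher with miR-34a, a microRNA generally described as restraining proliferation. Scaling of the arrays is argued against as the cause, since the median log2 change of all tested genes was -0.0097. The lowest G2/M median over quantile, median and cyclic loess normalization was 2.355. These normalizations add little to the argument, since the arrays already had equal trimmed means and left them little to correct. A difference in RNA integrity stays open. The mean 3' to 5' ratios of the groups differed by 1.135 times for GAPDH and 1.068 times for actin. Both lay under the bound written for arguing against this cause, but beyond the spread between arrays. How far such a difference would move the cell cycle genes was not tested. Exchanged group labels cannot be told apart from correct ones. The 18 reported miR-34a targets found in no other list had a median of -0.23 ± 0.14 (bootstrap SE). It lay past the bound of random lists (-0.22 to 0.22) on the side correct labels would give. It did so by less than its SE, a requirement set after the median had been seen. This subset leaves out targets shared with any other list, the cell cycle lists among them. In it 2 rose and 3 fell, against 5 and 8 of all 37 tested targets. Some targets may also have been chosen from these same arrays, which would fix the side in advance. The median therefore cannot decide between the labels. An effect of miR-34a, and a difference in growth state between the cultures that has nothing to do with it, both stay open and were not tested, since each group may be 1 culture.

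The second pattern is the lower level of stress genes. An amino acid response through ATF4 in the empty vector culture was set against a response to misfolded protein in the endoplasmic reticulum. Cytosolic aminoacyl-tRNA synthetases, which ATF4 induces, had a median of -0.35 (percentile 0.07; 7 of 17 fell and 2 rose), led by AARS1 (-1.49). The 16 tested ER chaperones had a median of 0.12 (percentile 80.85) but went both ways, with 2 rising and 3 falling, from DNAJB9 (-1.28) to SDF2L1 (1.36). The 9 in no list above had a median of 0.0084 (percentile 50.5) with 0 rising and 2 falling. As sets, the synthetases lay below the central range of their random lists (-0.19 to 0.28) and the ER chaperones within theirs (-0.21 to 0.26). This is the order an amino acid response would give, and the ER chaperones were not lower as a set. The rule written for an amino acid response asked only for that order of the sets, so it was met. It did not weigh single chaperones, but since 3 of them fell, a response to misfolded protein is not ruled out. Scaling is argued against here too by the median log2 change of all tested genes (-0.0097). The highest median of the stress list over the 3 normalizations was -0.77, but they had little to correct and so add little. Depleted medium in the empty vector culture and an effect of miR-34a were not tested and stay open.

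The last pattern, looked for after some neighbouring genes were seen among the largest falls, is that neighbouring genes move together, as a difference in copy number between the cell populations would bring about. Over windows of 21 neighbouring tested genes, ordered by the GRCh38.p14 gene table, the largest absolute median log2 change was 0.487. It lay above the largest of 93.7% of 1000 shuffles of the gene order, whose 95th percentile was 0.495. Copy number therefore cannot be told apart from chance with this test, which fell between the bounds set for it.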
